A study of Homo sapiens with 32 samples.

How the data were processed

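Single-cell RNA counts of PBMCs from 8 participants, 4 in habitual sleep and 4 in sleep restriction, each in 4 GEM wells, were analysed. Per the labels' protocols, mononuclear cells were separated by density gradient, frozen, tagged with sample barcodes (CellPlex) and made into 10x 3' v3 libraries, a design that counts 3' ends of polyadenylated RNA. Per the submitters' processing notes, the authors used Cell Ranger 6.1.2 with GRCh38; the annotation release and the settings for calling cells and assigning tags are not given in the sources used here. The deposited values are raw UMI counts per gene and barcode, per the file headers and the whole-number values, 1 matrix per participant and well. Each matrix held 36601 genes and 12 rows of sample-tag counts, and the tag rows were kept out of all gene totals. The 132 sex-linked rows (Y-linked genes, XIST and TSIX) were taken out before any test. Gene positions were taken from GENCODE release 29 on GRCh38, matched by Ensembl gene identifier. No barcode was shared by 2 participants of 1 well. Assigning tags removes many pairs of cells from different participants but not pairs from 1 participant.

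Barcodes with at least 200 genes, at least 500 UMIs and under 15% mitochondrial UMIs were kept. Of 25818 barcodes, 9649 were at or over the mitochondrial limit, 2001 were under the gene limit and 0 under the UMI limit, and the lowest barcode held 500 UMIs, so a UMI limit had been met before deposit. The loss was uneven, with 22.7% of barcodes kept in habitual-sleep participant 1 and 61.4% to 89.0% in the others. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours fed Leiden clustering at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6). No authors' cell annotation was used here. A cluster was named from fixed markers if at least 3 of them were among its 60 leading genes and no other class had more among its 10 leading genes. A cluster of shallow cells also needed at least 1 marker of the class among its 10 leading genes. The names mean that a cluster is CD4 T cell-like, monocyte-like and so on, and the suffix is dropped. Cluster 17 (114 shallow cells) and cluster 19 (68 cells led by immunoglobulin genes and MKI67) stayed unnamed. Classes were tested when at least 3 participants per group had at least 20 cells, except that 2 habitual-sleep participants remained in the alternative without participants 1 and 4. Monocytes are classical plus nonclassical monocytes, and dendritic cells are conventional plus plasmacytoid. Scrublet, run per well, marked 27 of 16169 cells (0.167%), too few to count as a working doublet call. An alternative therefore left out the cells with the highest 5% of doublet scores in each well.

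Counts of a class were summed over all cells and wells of a participant, so that the participant was the replicate (n = 4 per group) and every well contributed to both groups. Sums were tested with edgeR 4.0.16 (quasi-likelihood F-test with robust fitting, TMM factors, filterByExpr, R 4.3.3), with Benjamini-Hochberg adjustment over the genes tested in the class and a threshold of 0.05. Fold changes are sleep restriction over habitual sleep. Shares of cells and depth per cell were tested with two-sided exact permutation tests over 70 relabellings (scipy 1.17.1, pandas 2.3.3), the shares adjusted over the family of 9. For 35 gene lists, covering inflammation, interferon, antigen presentation, stress hormones, the circadian clock, metabolism and markers of other cells, camera (limma 3.58.1) was run with a preset correlation of 0.01 on lists with at least 5 tested members, 34 of them in monocytes; estimated correlations and fry were run beside it. Camera compares a list with all other genes, so a list can pass without any member passing. A count adjusted over the list alone uses the Benjamini-Hochberg adjustment within that list. Differences in response between classes used limma on within-participant differences of log2 CPM with a prior count of 2. NK marker UMIs were summed over the fixed NK marker list, and cells with 5 or more of them were counted.

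The groups, tests, lists, markers, alternatives and the rule for named genes were fixed before the data were examined. The rule took, in monocytes, up to 12 rising and 12 falling genes past the threshold, or else 5 each way as genes that did not pass, up to 4 members of smallest p per list, a panel of 18 genes, and up to 4 rising and 4 falling genes past the threshold in each other class and class difference. The members named for 15 of the lists are given here. Immunoglobulin and T cell receptor segments and genes whose level follows genotype or haplotype (several HLA and KIR genes, for example) were tested but not named, and neither was any gene in which participants of both groups fell on 2 levels at least log2 3 apart. Results of a few of the tested genes are not reported here. No sequence variants were examined.

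Alternatives covered DESeq2 1.42.0, limma-voom, other normalization factors, filters on low counts (none, or at least 50 counts in 4 participants), stricter cell limits (1000 UMIs, 10% mitochondrial), every deposited barcode, Leiden resolution 0.5, doublets, equal cell numbers, single wells, wells kept separate with the participant as random effect, and leaving out each participant. Added after the data were seen were the alternatives without the highest doublet scores, without habitual-sleep participants 1 and 4 together, with stricter cells and without habitual-sleep participant 1, and with other factors before camera, and for NK marker UMIs the runs without each participant. The tests were also run on 5 simulated data sets per class with 200 genes changed by 1.5-, 2- or 4-fold. In simulated monocytes, 9.2 unchanged genes per data set were called on average. Camera called 32 of 34 lists raised 1.5-fold there. Genes were simulated independently of each other, so that count does not hold for lists whose members are correlated. Participants held 10082586 to 21889257 UMIs each. Figures were drawn with matplotlib 3.10.9.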

Results

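Peripheral blood mononuclear cells (PBMCs), the monocytes, lymphocytes and dendritic cells recovered from blood on a density gradient, were profiled by droplet single-cell RNA sequencing in 8 participants. Participants 1 to 4 were sampled in a habitual-sleep phase, with a group sleep duration of 7.5 ± 0.1 h per night, and participants 5 to 8 in a sleep-restriction phase, with 6.2 ± 0.1 h per night (the series does not say what kind of error these are). The study was a crossover, but the series describes the 8 participants as distinct and the labels pair none of them. The groups were therefore compared unpaired, with n = 4 each. Frozen cells of all 8 participants were tagged, pooled and loaded into 4 GEM wells, the separate droplet reactions of the instrument, which gave 32 count matrices, 16 per group. Total UMI counts (unique molecular identifiers, one per captured transcript) over the 4 wells were 21889257, 10278395, 14851646 and 17999923 for habitual-sleep participants 1 to 4 and 10588194, 12638608, 10082586 and 18914278 for sleep-restriction participants 5 to 8. Single matrices held between 2282478 and 5732040 UMIs.

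Of 25818 barcodes, 16169 (62.6%) passed the limits on genes, UMIs and mitochondrial transcripts. The share kept was 58.7% ± 26.4 (SD, n = 4) in habitual sleep and 86.6% ± 2.63 in sleep restriction (two-sided exact permutation p = 0.0857). It was 22.7% in habitual-sleep participant 1, whose median barcode carried 32.4% mitochondrial UMIs, and 61.4% to 86.0% in the other 3 participants of that group. The kept cells fell into 21 clusters. These included CD4 T cells (4288 cells), CD8 T cells (2902), classical monocytes (2652), which carry CD14 and the S100A8 and S100A9 alarmins, NK cells (1820), B cells (1574) and nonclassical monocytes (1520), which carry the Fc receptor FCGR3A. Some monocyte clusters belonged mostly to single participants. Habitual-sleep participant 4 gave 84.9% of the 808 cells of classical cluster 9, whose leading genes included TMEM176B, SGK1, FOS and IER3. Participant 1 gave 52.2% of nonclassical cluster 5 and 55.8% of nonclassical cluster 13, whose leading genes included EGR1.

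The first comparison asked whether the make-up of the PBMCs differed with sleep. Monocytes made up 31.3% ± 21.3 (SD, n = 4) of kept cells in habitual sleep and 20.8% ± 10.0 in sleep restriction (exact permutation p = 0.429). Classical monocytes stood at 15.5% ± 12.8 and 15.5% ± 7.61 (exact p = 1), nonclassical monocytes at 15.8% ± 24.4 and 5.27% ± 2.92 (exact p = 0.771). NK cells, cytotoxic innate lymphocytes, made up 6.96% ± 4.05 and 14.2% ± 6.66 (exact p = 0.171). CD4 T cells were at 24.7% ± 14.8 and 28.3% ± 3.08 (exact p = 0.629), CD8 T cells at 15.9% ± 7.79 and 20.6% ± 8.14 (exact p = 0.429), B cells at 9.60% ± 4.27 and 9.54% ± 4.70 (exact p = 0.943), and dendritic cells at 4.72% ± 4.89 and 2.60% ± 1.05 (exact p = 0.629). Among monocytes, the nonclassical share was 34.9% ± 37.9 and 25.7% ± 5.35 (exact p = 0.971). None of these 9 differences passed (adjusted p = 1 for each of the 9), and 0.0286 is the smallest two-sided p that 70 relabellings allow. The nonclassical spread in habitual sleep came from participant 1, at 52.3% against 1.08% to 5.53% in the others. Without that participant the difference in nonclassical share turned from -10.6 to 1.59 percentage points. The differences in the shares of monocytes and CD8 T cells then shrank from -10.5 to -1.88 and from 4.69 to 0.844 percentage points.

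**Figure D1:**
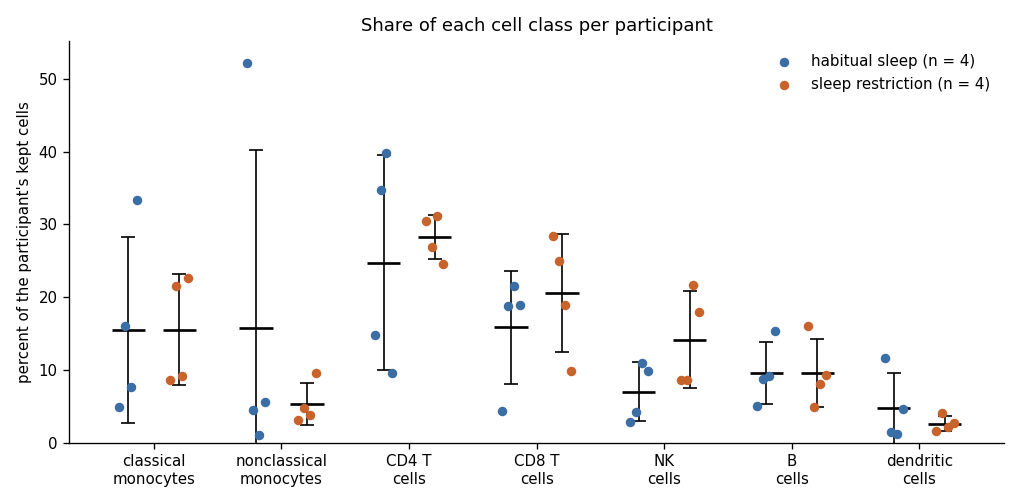
Share of each cell class, in percent of a participant's kept cells, for habitual sleep (blue) and sleep restriction (orange). Points are participants (n = 4 per group), bars are means and whiskers are 1 SD; the nonclassical point at 52.3% is habitual-sleep participant 1, and the groups overlap in every class shown.

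The series asks whether sleep shapes the transcription of monocytes. Summed over all monocytes of a participant, no gene differed between the groups past the threshold. The genes of smallest p that were higher in sleep restriction included PRICKLE1, a planar cell polarity gene, at 2.27 ± 1.02 CPM (library-scaled counts) in habitual sleep and 6.63 ± 1.804 in sleep restriction (log2 fold change 1.68, SE 0.37), IGFLR1, a receptor of the tumor necrosis factor receptor family (56.3 and 81.9 CPM, log2 0.55, SE 0.13), and PPDPF (251 and 342 CPM, log2 0.44, SE 0.11). CD7, a T and NK cell surface protein, stood at 6.44 and 12.4 CPM (log2 0.92, SE 0.24) and the noncoding AL592183.1 at log2 1.21 (SE 0.30). Lower in sleep restriction were CD55, which protects cells from complement, at 200.04 ± 13.4 and 137 ± 20.3 CPM (log2 -0.54, SE 0.13), SIRPB2 (36.8 and 23.8 CPM, log2 -0.62, SE 0.18), ANKRD28 (log2 -0.86, SE 0.24), KIF1BP (log2 -0.76, SE 0.21) and GTPBP8 (log2 -0.70, SE 0.19). None of these 10 genes passed (adjusted p = 1.00 by edgeR). Over all alternatives, the lowest adjusted p was 0.0406 for IGFLR1, 0.0405 for PPDPF and 0.0430 for CD55, so these passed in an alternative, but in no run without 1 participant. The edgeR quasi-likelihood test called 0 of 10538 genes, with 294 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Of the monocytes of habitual-sleep participant 1, 91.4% were nonclassical. Without that participant the edgeR test called 1 gene, with 549 at an unadjusted p under 0.05. On simulated data of the same depth, spread and number of participants, with 200 genes changed at once, the test recovered 13.4% of genes changed 1.5-fold, 56.1% of those changed 2-fold and 90.3% of those changed 4-fold. Changes near 1.5-fold were thus mostly not detected there. So many changed genes ease the Benjamini-Hochberg cutoff, so these shares are too high for data in which few genes change.

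In the fixed panel of monocyte and sleep-related genes, the inflammatory transcripts had lower means in sleep restriction but overlapped between the groups. The cytokine IL1B stood at 31.9 ± 20.9 CPM in habitual sleep and 14.4 ± 10.6 in sleep restriction (log2 -1.13, SE 0.66), the chemokine CCL3 at 47.7 ± 41.1 and 10.0 ± 8.32 (log2 -2.10, SE 0.87), CXCL8 at log2 -1.42 (SE 1.22) and TNF at log2 -0.68 (SE 0.82). TNF turned to 0.61 without habitual-sleep participant 4. The alarmins S100A8, S100A9 and S100A12 had log2 values of -0.23, -0.20 and -0.43, and their sign turned under limma-voom, as did those of NFKBIA, FCGR3A, CCR2, CX3CR1 and NR1D2 given next. Estimates of subset markers lay near 0, some with a wide error. They were 0.04 (SE 0.38) for CD14, -0.19 (SE 0.63) for FCGR3A and -0.05 (SE 0.41) for CCR2. CX3CR1 was at 0.01 (SE 0.24) and HLA-DRA at -0.05 (SE 0.18). Of the monocytes of habitual-sleep participant 1, 91.4% were nonclassical, against 12.4% to 21.7% in the others of that group. The monocyte sums thus mix the 2 subsets unequally, and a value near 0 does not show that the groups are alike. FCGR3A turned to 0.76 and CD14 to -0.23 without habitual-sleep participant 1. Genes that respond to glucocorticoids or follow the circadian clock also had estimates near 0. FKBP5 was at 0.10 (SE 0.17), TSC22D3 at -0.06 (SE 0.15), PER1 at 0.15 (SE 0.29) and NR1D2 at 0.02 (SE 0.28). The phosphatase DUSP1 was at -0.72 (SE 0.48). NFKBIA, the inhibitor of NF-kB, was at -0.06. None of the 18 panel genes passed (adjusted p = 1.00 by edgeR).

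Gene lists gave a finer view of the same monocytes, and 7 of 34 lists passed camera's threshold with its preset correlation of 0.01. Of the 35 splits of the 8 participants into 2 groups of 4, the real one included, 31 gave at least as many lists, so chance cannot be excluded. Genes of the cytosolic ribosome were higher in sleep restriction in 78 of 78 members (median log2 0.20, adjusted p = 5.39e-21), among them RPS10 at log2 0.46 (SE 0.18), RPL8 at 0.28, RPLP0 at 0.32 and RPS19 at 0.40. Nuclear genes of oxidative phosphorylation were higher in 45 of 55 members by a small amount (median log2 0.07, adjusted p = 0.00104), with NDUFB7 at 0.21, ATP5PO at 0.22, ATP5F1D at 0.22 and SDHB at 0.18. Immediate-early and AP-1 genes, which respond within minutes to stimulation and to handling of cells, were lower in 20 of 23 members (median log2 -0.45, adjusted p = 0.00226), with EGR1 at -1.43 (SE 0.61), MAFF at -1.18 (SE 0.48) and BTG2 at -0.59 (SE 0.24) and KLF10 going the other way at 0.34 (SE 0.16). With an estimated correlation none of the 7 lists held: adjusted p = 0.788 for the ribosomal list, adjusted p = 0.880 for oxidative phosphorylation and adjusted p = 0.809 for the immediate-early list. Each of these 3 lists had 0 members past the threshold over all genes and 0 adjusted over the list alone. Over all alternatives, the lowest adjusted p over all genes was 0.0406 for RPS10 and 0.0411 for RPL8, so both passed in an alternative. The immediate-early call ended without habitual-sleep participant 4 (median -0.13, adjusted p = 0.938), who gave most of cluster 9, and without participant 2 (adjusted p = 0.0641). The call for oxidative phosphorylation ended without habitual-sleep participant 1 (median 0.02, adjusted p = 0.490) and without sleep-restriction participant 6 (adjusted p = 0.0967). The ribosomal list passed in each of the 8 runs that left out 1 participant. Its median ran from 0.10 without habitual-sleep participant 1 to 0.30 without participant 4.

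The other 4 lists that passed hold transcripts of other cell types. Cytotoxic effector genes were higher in 16 of 20 members (median log2 0.60, adjusted p = 8.59e-07), with NKG7 at log2 0.89 (SE 0.27), GNLY, which encodes the granule protein granulysin, at 1.24 (SE 0.38), GZMA at 1.10 (SE 0.38) and GZMH at 1.12 (SE 0.51). NK cell markers were higher in 7 of 9 members (median log2 0.74, adjusted p = 8.02e-06), T cell markers in 13 of 15 (median log2 0.33, adjusted p = 6.56e-06) and platelet markers in 10 of 10 (median log2 0.49, adjusted p = 0.00226). With an estimated correlation the cytotoxic and NK lists each had adjusted p = 0.596, and the T cell and platelet lists each had adjusted p = 0.788. Over all genes 0 members of these lists passed. Adjusted over the list alone, 2 NK cell markers (NKG7 and GNLY) and 1 T cell marker (CD7) passed, and 0 members of the cytotoxic and platelet lists. When cells with the highest 5% of doublet scores were left out, a step chosen after the data were seen, the medians of the cytotoxic, T cell and NK lists were -0.02, -0.13 and -0.02 in monocytes, and the 3 calls ended (adjusted p = 0.689, 0.469 and 0.885). The T cell call also ended without habitual-sleep participant 4 (adjusted p = 0.0917) or sleep-restriction participant 5 (adjusted p = 0.0538), and the platelet call without habitual-sleep participant 1 (adjusted p = 0.438) or sleep-restriction participants 5 (adjusted p = 0.305) or 6 (adjusted p = 0.0589). With habitual-sleep participants 1 and 4 left out together, also chosen after the data were seen and leaving 2 participants in that group, the ribosomal and NK marker lists passed in monocytes (adjusted p = 3.08e-16 and 0.031), and the immediate-early, oxidative phosphorylation, cytotoxic, T cell and platelet lists did not (adjusted p = 0.941, 0.0973, 0.101, 0.731 and 0.762). In that setting 11 lists passed in all, 4 higher and 7 lower, and only these 2 had passed with all participants. Over all alternatives run, adjusted p went from 3.27e-35 to 0.914 for the ribosomal list, 9.15e-06 to 0.914 for oxidative phosphorylation, 4.66e-17 to 0.972 for immediate-early genes, 3.18e-15 to 0.914 for cytotoxic genes, 2.33e-15 to 0.914 for NK markers, 1.36e-10 to 0.914 for T cell markers and 1.58e-06 to 0.914 for platelet markers.

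The lists written for inflammation, stress hormones and the clock did not pass in monocytes with all participants. Lists other than the 7 above did pass in some alternatives. Without habitual-sleep participant 1, 11 lists passed, 5 of them among the 7. Without habitual-sleep participant 3, 12 passed, 7 of them among the 7. The values that follow are those with all participants. The TNF and NF-kB list was lower in 17 of 23 members (median log2 -0.06, adjusted p = 0.476), with PTGS2 at -1.45 (SE 0.55), CD83 at -0.91 and BCL2A1 at -0.63. The list of inflammatory cytokines and chemokines was lower in 11 of 15 (median -0.39, adjusted p = 0.235), with CCL2 at -0.70 and CCL5 at 0.64. Type I interferon response genes were lower in 18 of 34 (adjusted p = 0.446), with IFIT2 at -0.91 (SE 0.35), IFIT1 at -0.72, SAMD9 at -0.35 and IRF9 at -0.21, and interferon-gamma response genes in 18 of 23 (adjusted p = 0.0777), with CXCL10 at -2.02 (SE 0.96), ANKRD22 at -0.78, IRF1 at -0.29 and CIITA at 0.23. Toll-like receptor signalling had adjusted p = 0.0777, with TLR1 at -0.48 (SE 0.16), TLR6 at -0.48, TICAM1 at -0.36 and TLR2 at -0.24. Heat shock genes had adjusted p = 0.0534. The glucocorticoid list (adjusted p = 0.901) included THBD at -0.92 (SE 0.31), MAP3K6 at 0.59 and ZBTB16 at 0.37. The circadian list (adjusted p = 0.293) included BHLHE40 at -0.53 (SE 0.18), NFIL3 at -0.45, PER2 at -0.38 and CLOCK at -0.34. The beta-adrenergic list (adjusted p = 0.667) included PRKACB at 0.48 (SE 0.13) and CREM at -0.36. Each of these lists had 0 members past the threshold over all genes and 0 adjusted over the list alone. Among markers of other cells, B cell markers (adjusted p = 0.165), neutrophil markers (adjusted p = 0.901) and dendritic cell markers (adjusted p = 0.667) did not pass. The other lists had adjusted p = 0.443 for MHC class II, 0.811 for MHC class I, 0.954 for classical monocyte alarmins, 0.792 for nonclassical monocyte genes, 0.446 for adhesion, 0.293 for the inflammasome, 0.811 for phagocytosis, 0.667 for the unfolded protein response, 0.811 for oxidative stress, 0.811 for glycolysis, 0.792 for mitochondrially encoded transcripts, 0.331 for cholesterol handling, 0.476 for chromatin modifiers, 0.686 for lymphocyte activation and 0.645 for the cell cycle. For 7 of the 34 lists (both MHC lists, alarmins, nonclassical monocyte genes, oxidative stress, glycolysis and cell cycle), none of them called, the median, the mean and the test differed in sign.

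**Figure D2:**
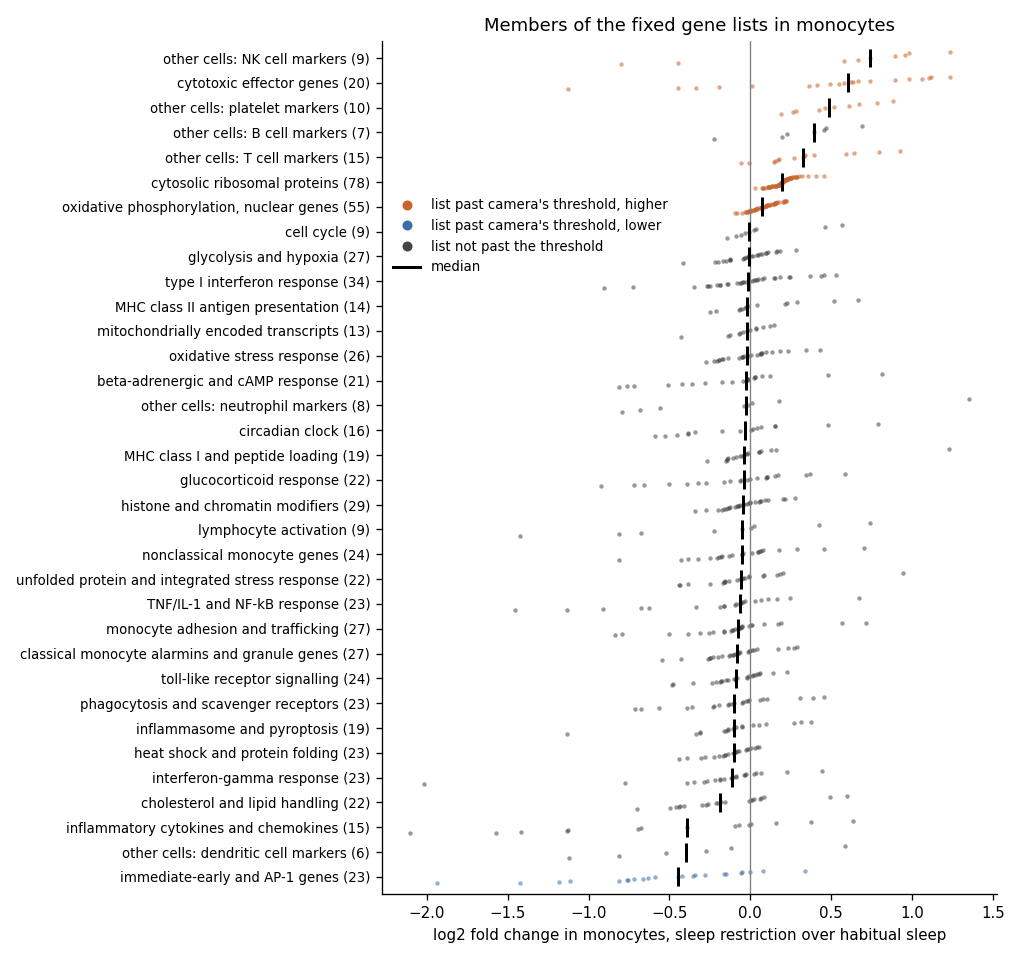
Log2 fold change in monocytes (sleep restriction over habitual sleep) of each tested member of the 34 gene lists, 1 point per gene, with the number of members in brackets and a bar at the median. Lists past camera's preset-correlation threshold are orange (higher) or blue (lower), while with an estimated correlation 0 of the 34 passed. Of the ribosomal protein genes 78 of 78 lie above 0, and of the immediate-early genes 20 of 23 lie below 0.

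Within classical monocytes, the inflammatory cytokine list was lower in 10 of 12 members (median log2 -0.38, adjusted p = 0.00284), and it kept its call whichever participant was left out. Immediate-early genes were lower in 19 of 21 members (median -0.51, adjusted p = 9.58e-04) and alarmins and granule genes in 21 of 26 (median -0.15, adjusted p = 0.0171). Adhesion and trafficking genes were lower in 18 of 25 (median -0.12, adjusted p = 0.0393). Ribosomal protein genes were higher in 75 of 78 (median 0.12, adjusted p = 1.45e-09) and B cell markers in 5 of 5 (median 0.88, adjusted p = 1.09e-04). Run with an estimated correlation, these had adjusted p = 0.354, adjusted p = 0.742, adjusted p = 0.742, adjusted p = 0.474, adjusted p = 0.742 and adjusted p = 0.354 in that order. Adjusted over the list alone, the lectin receptor CLEC4D at log2 -0.72 (SE 0.19), the phosphatase DUSP2 at -1.09 (SE 0.31) and the B cell receptor component CD79B at 0.88 (SE 0.25) passed, genes singled out after their values were seen, and over all genes 0 passed. Over all alternatives, the lowest adjusted p over all genes was 0.0376 for DUSP2, 0.106 for CLEC4D and 0.203 for CD79B, so DUSP2 passed in an alternative. The edgeR test called 0 of 9197 genes (388 at an unadjusted p under 0.05), as did DESeq2 and limma-voom. In classical monocytes the immediate-early call ended without habitual-sleep participant 4 (adjusted p = 0.467), the alarmin call without habitual-sleep participant 3 (adjusted p = 0.8293) or sleep-restriction participant 7 (adjusted p = 0.181), and the adhesion call without habitual-sleep participants 2 or 3 (adjusted p = 0.2001 and 0.337) or sleep-restriction participants 5 or 7 (adjusted p = 0.153 and 0.168).

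In nonclassical monocytes, cytotoxic transcripts had a higher mean in sleep restriction. The sums rested on 809, 70, 27 and 124 cells of habitual-sleep participants 1 to 4 and 53, 88, 65 and 284 cells of sleep-restriction participants 5 to 8. The sum of participant 3 held 186886 UMIs, so a value of a few CPM there rests on very few UMIs. In participants 5 and 7, 246 of 300 and 225 of 280 NK marker UMIs lay in 5 and 7 cells. Of 10 cytotoxic effector genes tested, 9 were higher, with a median log2 of 1.54 (adjusted p = 9.62e-10, and adjusted p = 0.171 with an estimated correlation). GNLY stood at 37.0 ± 14.5 CPM (SD, n = 4) in habitual sleep and 191 ± 81.1 in sleep restriction (log2 2.59, SE 0.58), GZMA at 6.57 and 39.0 CPM (log2 2.63, SE 0.59), CCL5 at 28.0 and 91.8 CPM (log2 1.64, SE 0.43), KLRD1 at log2 1.97 (SE 0.47) and NKG7 at log2 1.66 (SE 0.55). These 5 genes passed adjusted over the list alone and were singled out after their values were seen, while over all genes 0 passed. Each passed over all genes without sleep-restriction participant 8 (adjusted p from 4.98e-07 for GNLY to 0.0354 for GZMA and KLRD1 in nonclassical monocytes), and some did with DESeq2, no filter, stricter cells or Leiden resolution 0.5. NK marker UMIs in these cells were at 1.77 ± 0.56 per 10000 in habitual sleep and 4.79 ± 2.05 in sleep restriction (exact p = 0.0571). In dendritic cells, which pool conventional and plasmacytoid cells, they were at 2.79 ± 1.57 and 4.76 ± 1.16 (exact p = 0.0857). There habitual-sleep participant 1, with 175 conventional and 6 plasmacytoid cells, was at 0.577. Of the dendritic NK marker UMIs, 80.9% lay in 28 of 336 cells in habitual sleep and 90.8% in 42 of 218 in sleep restriction. Whether these were plasmacytoid cells was not tested. Classical monocytes did not show the rise of nonclassical ones, at 0.868 ± 0.302 and 0.827 ± 0.163 (exact p = 0.971). Of the sleep-restriction group's NK marker UMIs in nonclassical monocytes, 77.8% lay in 46 of 490 cells (9.39%) with 5 or more of them, against 28.6% in 41 of 1030 cells in habitual sleep (44.2% in 10 of 221 cells without participant 1). Sleep-restriction participant 6 gave 25 of the 46, and without that participant they were 21 of 402 cells (5.22%), while without participant 8 they were 37 of 206 (18.0%). A GNLY UMI was seen in 13.5% of nonclassical monocytes in habitual sleep and 12.4% in sleep restriction. With the highest 5% of doublet scores left out, the list in nonclassical monocytes had a median of 0.13 and no longer passed (adjusted p = 0.571), and with equal cell numbers per participant it had a median of 0.47 (adjusted p = 0.237).

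Nonclassical monocytes also had higher ribosomal protein genes in 78 of 78 members (median log2 0.23, adjusted p = 6.63e-17) and higher oxidative phosphorylation genes in 51 of 55 (median 0.19, adjusted p = 6.12e-09). Immediate-early genes were lower in 15 of 19 (median -0.18, adjusted p = 0.013). Cholesterol and lipid handling genes were lower in 14 of 17 (median -0.18, adjusted p = 0.0338), among them CPT1A, which brings fatty acids into mitochondria, at -0.70 (SE 0.24), which passed adjusted over the list alone and was named after its values were seen; over all genes 0 members passed. Under an estimated correlation, the first 3 lists each had adjusted p = 0.613 and the cholesterol list adjusted p = 0.378. The edgeR test called 0 of 7182 genes (305 at an unadjusted p under 0.05), DESeq2 called 4 and limma-voom 1. In nonclassical monocytes the immediate-early call ended without habitual-sleep participant 4 (adjusted p = 0.470) or sleep-restriction participant 7 (adjusted p = 0.0915), and the cholesterol call without habitual-sleep participants 1 or 4 (adjusted p = 0.266 and 0.0928) or sleep-restriction participant 7 (adjusted p = 0.176). Both calls in nonclassical monocytes also ended with equal cell numbers (adjusted p = 0.476 and 0.543) and without habitual-sleep participants 1 and 4 together (adjusted p = 0.193 and 0.320). The cholesterol call ended without the highest doublet scores as well (adjusted p = 0.137).

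Response here means the difference between the groups of people, since each participant was sampled in 1 sleep phase. Whether it differed between classes was tested on within-participant differences between classes. GNLY responded less in classical than in nonclassical monocytes, by log2 -2.26 (SE 0.30, limma adjusted p = 0.00167), and it passed in each of the 8 runs without 1 participant. This comparison was not rerun without the highest doublet scores. GNLY lies on chromosome 2 from 85685175 to 85698854 on the plus strand (GRCh38, GENCODE release 29, ENSG00000115523). It was the 1 gene called of 7109, with 414 at an unadjusted p under 0.05. Fitted as an interaction in edgeR, 3 genes passed, the noncoding AL360012.1, GNLY and the chemokine CCL5. GNLY is a transcript of NK cells, where it stood at 14401 CPM over the summed UMIs of sleep restriction, against 137 in nonclassical and 26.2 in classical monocytes of that group. Between monocytes and lymphocytes, limma called 0 of 9888 genes (459 at an unadjusted p under 0.05), and the edgeR interaction also called 0. On simulated data with 200 genes changed at once, that comparison recovered 32.2% of genes that changed 2-fold in one class and 83.3% of those that changed 4-fold.

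B cells were the 1 class in which edgeR called genes between the groups. DSP, which encodes the desmosomal plaque protein desmoplakin, fell by 2.62 on the log2 scale (SE 0.38, edgeR adjusted p = 5.27e-04), from 28.3 ± 4.68 CPM (SD, n = 4) in habitual sleep to 4.14 ± 3.99 in sleep restriction. The habitual-sleep values of DSP rested on 115 UMIs in 91 of 792 B cells. Those of sleep restriction rested on 19 UMIs in 19 of 782 B cells, so single participants there had few UMIs. CLECL1, which encodes a C-type lectin-like protein of B cells and dendritic cells, rose by log2 1.195 (SE 0.19, edgeR adjusted p = 0.00167), from 34.7 ± 8.69 to 76.4 ± 5.29 CPM. The values of the 4 participants of one group did not overlap those of the other for either gene. Both genes were called from these same values, so this adds no separate evidence. DSP (ENSG00000096696) lies on chromosome 6 from 7541575 to 7586717 on the plus strand, and CLECL1 (ENSG00000184293) on chromosome 12 from 9715860 to 9733299 on the minus strand. Whether B cells differed in this from other classes was not tested. These were 2 of 6875 genes tested, with 395 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 2. DSP passed whichever participant was left out. CLECL1 did not pass without habitual-sleep participant 4 (log2 0.98, adjusted p = 0.0665), and neither gene passed with equal cell numbers per participant (DSP -2.25, adjusted p = 0.160, and CLECL1 0.65, adjusted p = 0.708). Over all alternatives, the adjusted p of DSP in B cells ran from 2.19e-09 to 0.160 and that of CLECL1 in B cells from 6.22e-06 to 0.754. Within GEM wells 1 to 4 alone, CLECL1 was at log2 1.66, 1.11, 1.02 and 1.10 (adjusted p = 0.239, 0.754, 0.605 and 0.754), and DSP, too rare to be tested in wells 1 to 3, was at -3.01 in well 4 (adjusted p = 0.138).

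**Figure D3:**
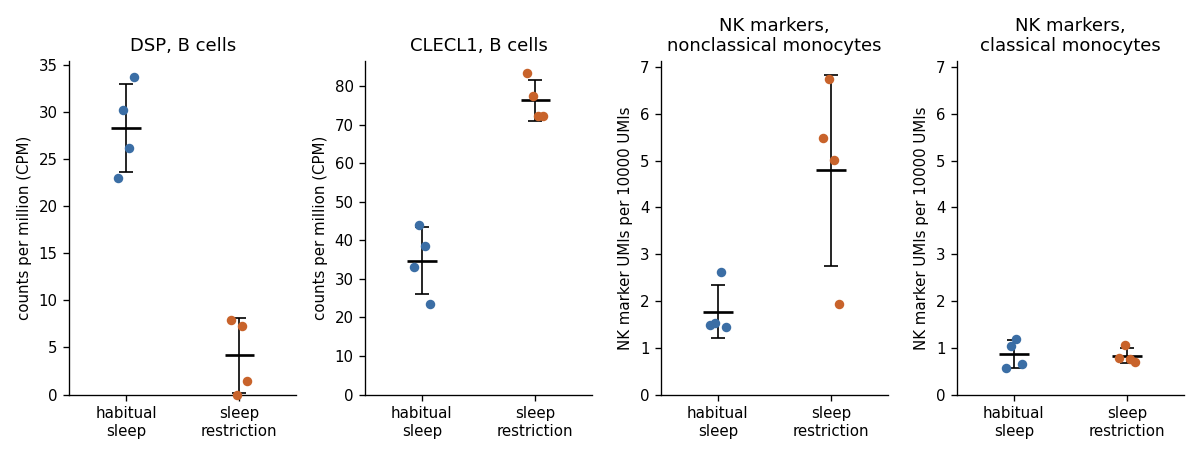
Levels of DSP and CLECL1 in B cells, in CPM, and of NK marker UMIs per 10000 UMIs in nonclassical and classical monocytes, per participant. Points are participants (n = 4 per group), bars are means and whiskers are 1 SD; the groups do not overlap for DSP and CLECL1, while sleep-restriction participant 8, at 1.93 NK marker UMIs per 10000 in nonclassical monocytes, lies within the habitual-sleep range.

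In NK cells, oxidative phosphorylation genes were higher in 52 of 55 members (median log2 0.21, adjusted p = 7.36e-10), cytotoxic effector genes in 19 of 24 (median 0.18, adjusted p = 0.00302) and NK markers in 9 of 12 (median 0.29, adjusted p = 0.0242). When the correlation was estimated, these had adjusted p = 0.670, adjusted p = 0.670 and adjusted p = 0.653. In B cells, oxidative phosphorylation genes were higher in 52 of 55 (median 0.15, adjusted p = 4.65e-07), ribosomal protein genes in 74 of 78 (median 0.10, adjusted p = 4.32e-04) and oxidative stress genes in 16 of 22 (median 0.09, adjusted p = 0.0107). Mitochondrially encoded transcripts were lower in B cells in 13 of 13 (median -0.14, adjusted p = 0.0107) and histone and chromatin modifiers in 18 of 25 (median -0.18, adjusted p = 0.0459). With the correlation estimated, the ribosomal list had adjusted p = 0.763 and the other 4 lists of B cells adjusted p = 0.481. Of these lists, members passed adjusted over the list alone only in the oxidative stress list, among them PRDX2 at log2 0.52 (SE 0.16), named after its values were seen, and over all genes 0 passed. In NK cells, the cytotoxic call ended without habitual-sleep participant 1 (adjusted p = 0.0501) or sleep-restriction participant 6 (adjusted p = 0.0541), and the NK marker call without habitual-sleep participants 2 or 4 (adjusted p = 0.0639 and 0.0713) or sleep-restriction participants 6 or 8 (adjusted p = 0.0541 and 0.0719). In B cells, the ribosomal call ended without habitual-sleep participants 1 or 3 (adjusted p = 0.770 and 0.0654), the oxidative stress call without habitual-sleep participants 1 or 3 or sleep-restriction participant 6 (adjusted p = 0.0815, 0.0654 and 0.0837), the mitochondrial call without habitual-sleep participant 4 or sleep-restriction participants 6 or 8 (adjusted p = 0.0976, 0.0648 and 0.155), and the histone call without habitual-sleep participants 1 or 3 or sleep-restriction participants 5, 6 or 7 (adjusted p = 0.152, 0.0943, 0.123, 0.0837 and 0.0919).

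In CD4 T cells, mitochondrially encoded transcripts were lower in 13 of 13 members (median log2 -0.24, adjusted p = 2.09e-07), while nuclear oxidative phosphorylation genes were higher in 50 of 55 (median 0.08, adjusted p = 5.96e-05) and ribosomal protein genes in 71 of 78 (median 0.07, adjusted p = 3.01e-04). Given an estimated correlation, each had adjusted p = 0.897. CD8 T cells also had lower mitochondrially encoded transcripts in 13 of 13 (median -0.19, adjusted p = 0.00226), with higher cytotoxic effector genes in 20 of 24 (median 0.35, adjusted p = 9.25e-05), NK markers in 8 of 10 (median 0.55, adjusted p = 0.00226), MHC class II genes in 11 of 12 (median 0.25, adjusted p = 0.00583) and oxidative phosphorylation genes in 44 of 55 (median 0.06, adjusted p = 0.0192). At an estimated correlation, oxidative phosphorylation in CD8 T cells had adjusted p = 0.849 and the other 4 lists adjusted p = 0.731. The CD8 T cells pooled cluster 4, led by GZMK, cluster 7, led by GZMH, and cluster 8, whose leading genes included LRRN3 and LEF1. Habitual-sleep participant 3 gave 35.3% of cluster 8, and sleep-restriction participant 5 gave 24.8% of cluster 7. A different mix of these clusters was not separated from a different level per cell. In these lists of CD4 and CD8 T cells 0 members passed over all genes and 0 adjusted over the list alone. Without habitual-sleep participants 1 and 4 together, none of the 3 lists of CD4 T cells passed. The mitochondrial list had median -0.09 (adjusted p = 0.0889), oxidative phosphorylation adjusted p = 0.0705 and the ribosomal list adjusted p = 0.825. Over all barcodes, the median mitochondrial percent was 32.4, 7.32, 8.76 and 10.2 in habitual-sleep participants 1 to 4 and 6.66 to 7.80 in sleep restriction. In CD4 T cells, the oxidative phosphorylation call ended without habitual-sleep participant 1 (adjusted p = 0.0773), and the ribosomal call without habitual-sleep participants 1, 3 or 4 (adjusted p = 0.139, 0.0557 and 0.0547) or sleep-restriction participant 7 (adjusted p = 0.270). In CD8 T cells, the mitochondrial call ended without habitual-sleep participant 1 or sleep-restriction participant 8 (adjusted p = 0.0975 and 0.156), the cytotoxic call without habitual-sleep participant 3 (adjusted p = 0.0545), the NK marker call without habitual-sleep participants 2 or 3 (adjusted p = 0.243 and 0.0536), the MHC class II call without habitual-sleep participants 2 or 3 or sleep-restriction participant 8 (adjusted p = 0.213, 0.0910 and 0.360), and the oxidative phosphorylation call without habitual-sleep participants 1, 3 or 4 or sleep-restriction participant 7 (adjusted p = 0.403, 0.0605, 0.0625 and 0.0892).

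No single gene passed in the T, NK or dendritic cells. The edgeR test called 0 of 9653 genes in CD4 T cells (510 at an unadjusted p under 0.05), 0 of 8795 in CD8 T cells (332), 0 of 7055 in NK cells (502) and 0 of 6608 in dendritic cells (257), and DESeq2 and limma-voom called 0 in each of these 4 classes. In dendritic cells 0 of 31 lists passed. On simulated data with 200 genes changed at once, genes changed 4-fold were recovered in 90.6% of cases in CD4 T cells, 90.3% in CD8 T cells, 86.4% in NK cells and 86.4% in dendritic cells.

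Depth and quality per cell were compared as possible technical differences. The median monocyte held 8571 ± 841 UMIs (SD, n = 4) in habitual sleep and 7927 ± 1120 in sleep restriction (exact permutation p = 0.4). Mitochondrial UMIs made up 7.97% ± 1.24 and 7.70% ± 1.16 (exact p = 0.714) and ribosomal protein UMIs 16.3% ± 2.49 and 18.8% ± 0.954 (exact p = 0.143). Without habitual-sleep participant 4 the ribosomal difference grew from 2.47 to 3.29 percentage points (exact p = 0.0286, the smallest that 35 relabellings allow here). Over every deposited barcode, the median monocyte held 4004 UMIs in habitual sleep and 6796 in sleep restriction (exact p = 0.171). Mitochondrial UMIs there made up 24.4% ± 16.8 and 8.73% ± 1.79 (exact p = 0.114). Ribosomal protein UMIs made up 9.07% ± 6.79 and 17.5% ± 1.28 (exact p = 0.0857). These barcodes included a cluster of 2334, named classical monocyte, with a median of 83.9% mitochondrial UMIs, 64.6% of it from habitual-sleep participant 1.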

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

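The tests of other splits of the participants and the alternatives without the highest doublet scores and without single participants for NK marker UMIs were chosen only after the result was seen; the tests of free RNA and of NK cells inside the nonclassical clusters were stated before.

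GNLY responded less in classical than in nonclassical monocytes, by log2 -2.26, a difference that passed its own test but was not rerun without the highest doublet scores. Of the 35 splits of the participants into 2 groups of 4, 4 gave at least the 1 gene of the real split, with 1 gene as the highest of the others, so chance cannot be excluded. The wider pattern was the higher level of cytotoxic transcripts in nonclassical monocytes under sleep restriction, a log2 ratio of 1.34 for NK marker UMIs. Over the summed UMIs of each well it was 1.22, 1.39, 0.26 and 1.75 in GEM wells 1 to 4, so it was small in well 3. Dendritic cells had a log2 ratio of 1.07 (exact p = 0.0857), which fell to 0.42 without habitual-sleep participant 1 (exact p = 0.114), and GNLY went the other way there, from 34.3 to 15.5 CPM over the summed UMIs. Dendritic cells with 5 or more NK marker UMIs had a median of 9777 UMIs, against 13715.5 in the other dendritic cells. The plasmacytoid cluster had a median of 9519. Dendritic cells with 5 or more numbered 4, 4, 5 and 15 in participants 1 to 4 and 7, 13, 7 and 15 in participants 5 to 8. Plasmacytoid cells were close to that in number, at 6, 5, 7 and 11 and at 5, 14, 8 and 15. The dendritic ratio may thus follow the mix of dendritic cells. Whether these were the same cells was not tested. Free RNA in the wells would add NK marker UMIs to other cells of the same wells as well. The log2 ratio was -0.198 in B cells, where single participants varied widely, and -0.180 in CD4 T cells. Classical monocytes were at 0.868 ± 0.302 per 10000 (SD, n = 4) in habitual sleep and 0.827 ± 0.163 in sleep restriction, far from the rise in nonclassical monocytes. The bound set beforehand against free RNA, on the ratio in B cells, was met. But every well held cells of both groups, so free RNA would reach both alike. Ratios near 0 in other classes would then arise with or without it, so this test cannot weigh free RNA. By the same design, a supply shared by both groups would not by itself raise NK marker UMIs in the nonclassical monocytes of 1 group. NK cells or pairs of cells inside the nonclassical clusters are a candidate explanation: 77.8% of the sleep-restriction group's NK marker UMIs lay in cells with 5 or more of them, and the bound set for it was met. These were 9.39% of the group's nonclassical monocytes, or 5.22% without sleep-restriction participant 6 and 18.0% without participant 8, where the share of UMIs was 71.8% and 84.7%. In habitual sleep the share of UMIs was 28.6%, or 44.2% without participant 1. Over both groups, those cells had a median of 10242 UMIs against 8150 in the other nonclassical monocytes. Without the highest doublet scores the log2 fold of GNLY in nonclassical monocytes was 0.13. In the NK clusters, cells with 5 or more had a median of 4012.5 UMIs. But the median of 10242 pools both groups, and 31 of the 41 such cells in habitual sleep came from participant 1. A limit of 5 UMIs also picks deeper cells more readily. These depths therefore do not settle whether the sleep-restriction group's cells were single NK cells. Having 5 or more NK marker UMIs does not by itself identify an NK cell or a pair. It stays open whether single NK cells or pairs carried the signal, and an effect of sleep on a small set of nonclassical monocytes was not tested apart from these.

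Single participants lay apart from the rest of their group in 19 of 220 groups tested (8.64%), by a gap to the nearest participant that took most of the group's range; chance gives about 1 in 20. Habitual-sleep participant 1 lay apart in nonclassical share (52.3% against 1.08% to 5.53%, ratio of gap to range 0.913), in the nonclassical share of monocytes (91.4% against 12.4% to 21.7%, ratio 0.883, but 52.5% over every deposited barcode), in CD8 T cell share (4.33% against 18.7% to 21.5%, ratio 0.840) and in the median mitochondrial percent over all barcodes (32.4% against 7.32% to 10.2%, ratio 0.884). The classical share of this participant was 4.91% of kept cells and 35.7% over every deposited barcode. The barcodes were clustered anew there, and the classical monocytes include a cluster of 2334 barcodes with a median of 83.9% mitochondrial UMIs, so it stays open how far the limit changed this share. In monocytes of the same participant, S100A12 was lowest at 6.02 on the log2(CPM + 1) scale against 9.22 to 9.79 (ratio 0.849), SDHB was lowest (ratio 0.985), GTPBP8 was lowest (ratio 0.870) and KIF1BP was highest (ratio 0.841). Sleep-restriction participant 8 had 3572 barcodes against 1943 to 2105 in the others of the group (ratio 0.901), and was lowest in nonclassical monocytes for GNLY (6.15 against 7.82 to 7.92, ratio 0.944) and KLRD1 (3.19 against 4.34 to 4.53, ratio 0.857). Habitual-sleep participant 4 was lowest in monocytes for CD7 (ratio 0.897) and NKG7 (ratio 0.835). Sleep-restriction participant 5 was lowest in monocytes for IGFLR1 (ratio 0.853) and BHLHE40 (ratio 0.836), and sleep-restriction participant 6 was highest for BTG2 in monocytes (ratio 0.847) and PRDX2 in B cells (ratio 0.837). Habitual-sleep participant 3 was lowest for IRF1 in monocytes (ratio 0.843), and sleep-restriction participant 7 was highest for CD79B in classical monocytes (ratio 0.832).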

How the results depend on the processing

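The alternatives without the highest 5% of doublet scores, without habitual-sleep participants 1 and 4 together, with stricter cells and without habitual-sleep participant 1, and with RLE factors before camera were chosen only after the result was seen. Of 426 alternatives to the comparisons (counts, shares and depth), 333 kept their direction and side of the threshold or lay within 1.5 times of the main count, 67 moved, 25 turned direction and 1 newly passed. For shares, adjusted over 9, a single share cannot fall below adjusted p = 0.257, so keeping the side of the threshold says nothing about their stability. Of 2186 alternatives to 101 single genes and lists, 2048 kept direction and side, 79 turned direction in 24 of the 101, 37 lost a call and 22 gained one. DSP in B cells kept its direction wherever it was tested (log2 -3.32 to -2.23), and the shares of monocytes, NK cells and CD8 T cells kept theirs in each alternative, though not their size. No paired analysis was run, since the series describes 8 distinct participants, although the study was a crossover. Gene tests in wells alone were not run for nonclassical monocytes, NK cells and dendritic cells, nor stricter cells without habitual-sleep participant 1 for nonclassical monocytes, since too few participants had 20 cells. Genes changed 1.5-fold were recovered in 13.4% of simulated cases in monocytes, at the depth, spread and number of participants here. This held with 200 genes changed at once, and the share would be lower with few changed genes. Leaving out habitual-sleep participants 1 and 4 together leaves 2 participants in that group, fewer than the 3 otherwise required. Where a value below turned or a count moved, the cause was not tested, except that equal cell numbers, single wells and stricter filters leave fewer cells or genes by construction.

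Differences in the share of classical monocytes, main value 0.0526 percentage points, became -2.50 with stricter cells, -8.84 with every deposited barcode, -1.34 at Leiden resolution 0.5, -0.918 in GEM well 1 and -0.794 in GEM well 2. The share of B cells, main value -0.0578, became 1.08 with stricter cells, 0.0800 with every deposited barcode, 0.165 without the highest doublet scores, 0.0919 in GEM well 2 and 0.687 in GEM well 3. The share of NK cells, main value 7.20, was 8.505 with every deposited barcode and 9.43 in GEM well 2 (exact p = 0.0286 and adjusted p = 0.257 in both). Leaving out 1 participant gave ranges of -18.0 (without habitual-sleep participant 3) to -1.88 (without participant 1) for monocytes, main value -10.5, and 0.844 (without habitual-sleep participant 1) to 8.25 (without sleep-restriction participant 8) for CD8 T cells, main value 4.69. For NK cells it gave 4.71 (without sleep-restriction participant 7) to 9.07 (without participants 5 or 6). The other ranges were -3.47 (without habitual-sleep participant 1) to 6.02 (without participant 4) for classical monocytes, -2.21 (without sleep-restriction participant 5) to 1.86 (without habitual-sleep participant 4) for B cells, -15.5 (without participant 3) to 1.59 (without participant 1) for nonclassical monocytes, -16.8 to 9.57 (the same pair) for nonclassical among monocytes, -1.52 (without participant 4) to 8.55 (without participant 3) for CD4 T cells, and -3.30 (without participant 3) to 0.196 (without participant 1) for dendritic cells. The difference in UMIs per monocyte, main value -644, was 2792 with every deposited barcode, and those in mitochondrial and ribosomal percent -15.6 and 8.41. In runs without 1 participant, the UMI difference ran from -1096 (without sleep-restriction participant 6) to -285 (without habitual-sleep participant 4). Leaving out 1 participant, the difference in mitochondrial percent ran from -0.764 (without sleep-restriction participant 7) to 0.308 (without habitual-sleep participant 1), and that in ribosomal percent from 1.49 (without participant 1) to 3.29 (without participant 4).

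Counts of called genes moved with the filter, the model and single participants. With no filter on low counts the count was 22 in classical monocytes, 27 in nonclassical monocytes, 17 in CD4 T cells, 9 in CD8 T cells, 13 in NK cells, 13 in B cells and 22 in dendritic cells. With wells kept separate and the participant as random effect it was 8 in monocytes, 22 in classical and 6 in nonclassical monocytes, 31 in CD4 T cells, 10 in NK cells and 7 in B cells. With habitual-sleep participants 1 and 4 left out it was 4 in monocytes, 2 in classical and 1 in nonclassical monocytes, 24 in CD4 T cells, 18 in CD8 T cells, 7 in B cells and 4 in dendritic cells. With stricter cells and without habitual-sleep participant 1 it was 1 in monocytes, 1 in classical monocytes and 5 in B cells. Nonclassical monocytes gave 4 genes with DESeq2, 1 with limma-voom, 1 with stricter cells and 1 at Leiden resolution 0.5. B cells gave 0 with the stricter filter on low counts, 0 with equal cells, 0 in each of GEM wells 1, 2 and 3, and 1 in GEM well 4, and dendritic cells gave 1 with equal cells. Leaving out 1 participant gave 0 to 1 genes in monocytes (1 without habitual-sleep participant 1), 0 to 6 in classical monocytes (6 without habitual-sleep participant 3), 0 to 6 in nonclassical monocytes (6 without sleep-restriction participant 8, 2 without habitual-sleep participant 1), 0 to 1 in CD4 T cells, 0 to 5 in CD8 T cells (5 without habitual-sleep participant 4), 0 to 2 in NK cells (2 without habitual-sleep participant 3), 2 to 5 in B cells (5 without habitual-sleep participant 1 or sleep-restriction participant 7) and 0 to 2 in dendritic cells (2 without habitual-sleep participant 2). The difference between classical and nonclassical responses called 3 genes as an edgeR interaction and 1 to 2 without 1 participant (2 without sleep-restriction participant 8).

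Of the lists, 7 in monocytes and 27 in the other classes passed with the preset correlation; with an estimated correlation 0 and 0 passed, and with fry 0 and 0. Monocytes gave 4 lists without the highest doublet scores, 11 without habitual-sleep participants 1 and 4, and 6 (without habitual-sleep participant 4, or sleep-restriction participants 5 or 6) to 12 (without habitual-sleep participant 3) without 1 participant. The other classes gave 17 with equal cells, 54 without participants 1 and 4, and 27 to 46 (without habitual-sleep participants 3 or 4) without 1 participant. With equal cells, calls ended for immediate-early and adhesion genes in classical monocytes (adjusted p = 0.128 and 0.171), immediate-early, cholesterol and cytotoxic genes in nonclassical monocytes (0.476, 0.543 and 0.237), oxidative phosphorylation and ribosomal genes in CD4 T cells (0.0631 and 0.108), MHC class II and oxidative phosphorylation in CD8 T cells (0.121 and 0.339), cytotoxic genes and NK markers in NK cells (0.246 and 0.107), and oxidative stress, mitochondrial and chromatin lists in B cells (0.137 each). Without participants 1 and 4, they ended for immediate-early genes in classical monocytes (0.981), immediate-early and cholesterol genes in nonclassical monocytes (0.193 and 0.320), all 3 lists in CD4 T cells, oxidative phosphorylation and mitochondrial transcripts in CD8 T cells (0.775 and 0.343), NK markers in NK cells (0.0852), and mitochondrial, ribosomal and chromatin lists in B cells (0.0783, 0.749 and 0.0946). Without the highest doublet scores, they ended for cholesterol and cytotoxic genes in nonclassical monocytes (0.137 and 0.571) and chromatin modifiers in B cells (0.0504), and the last also with Scrublet's own calls left out (0.0729). B cell markers in classical monocytes had too few tested members in these settings except without participants 1 and 4. Without the highest doublet scores the median log2 fold in monocytes was -0.017 for cytotoxic effector genes, -0.13 for T cell markers and -0.017 for NK cell markers.

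Of the genes named in monocytes, none of which had passed in the main test, these turned direction (log2 fold). With stricter cells, CD14 was at -0.077 and FCGR3A at 0.025. Without the highest doublet scores, NR1D2 was at -0.0018, CCL5 at -0.077, BCL11B at -0.022 and KLRD1 at -0.017. With Scrublet's own calls left out, NR1D2 was at -0.0049. In GEM well 1, CD14 was at -0.0069, CCR2 at 0.19, PER1 at -0.14, CCL5 at -0.27, IFIT1 at 0.15, GNLY at -0.0010 and LTB at -0.063. In GEM well 2, CCR2 was at 0.049, CX3CR1 at -0.16, NR1D2 at -0.34 and IFIT1 at 0.62. In GEM well 3, CX3CR1 was at -0.025 and NR1D2 at -0.057. In GEM well 4, CD14 was at -0.13, HLA-DRA at 0.025, FKBP5 at -0.0069 and, in B cells, PRDX2 at -0.17. With the participant as random effect, NFKBIA was at 0.11, S100A8 at 0.31, S100A9 at 0.33, S100A12 at 0.26, FCGR3A at 0.087, CCR2 at 0.34, CX3CR1 at -0.016 and NR1D2 at -0.068. With limma-voom, NFKBIA was at 0.16, S100A8 at 0.092, S100A9 at 0.13, S100A12 at 0.014, FCGR3A at 0.28, CCR2 at 0.21, CX3CR1 at -0.0047 and NR1D2 at -0.077. With equal cells, CX3CR1 was at -0.025, FKBP5 at -0.087 and NR1D2 at -0.057. With stricter cells and without habitual-sleep participant 1, CD14 was at -0.32, FCGR3A at 0.98, TSC22D3 at 0.064 and PER1 at -0.086. Without habitual-sleep participants 1 and 4, TNF was at 1.02, NFKBIA at 0.30, CD14 at -0.25, FCGR3A at 0.81, HLA-DRA at 0.12 and TSC22D3 at 0.13.

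Leaving out 1 participant, the log2 fold in monocytes ran from -1.00 to 0.61 for TNF (0.61 without habitual-sleep participant 4), -0.30 to 0.51 for NFKBIA (0.51 without the same), -0.59 to 0.053 for S100A8 and -0.56 to 0.069 for S100A9 (highest without habitual-sleep participant 3), -0.23 to 0.31 for CD14 and -0.49 to 0.76 for FCGR3A (CD14 lowest and FCGR3A highest without habitual-sleep participant 1), -0.18 to 0.11 for HLA-DRA, -0.36 to 0.18 for CCR2, -0.17 to 0.22 for CX3CR1, -0.083 to 0.19 for FKBP5, -0.15 to 0.067 for TSC22D3, -0.0015 to 0.42 for PER1 and -0.15 to 0.25 for NR1D2.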

Other observations

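The tests of other splits, of the 2 habitual-sleep preparations and of depth per monocyte were chosen only after the result was seen, while the test of naive and memory B cells was stated before.

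In dendritic cells, which activate T cells, IL1B and CD83 had lower means in sleep restriction. IL1B stood at 42.6 ± 16.7 CPM (SD, n = 4) in habitual sleep and 17.1 ± 2.84 in sleep restriction (log2 -1.38, SE 0.28), and the maturation marker CD83 at 29.2 ± 17.1 and 15.8 ± 2.80 (log2 -1.12, SE 0.32). Both passed adjusted over the TNF and NF-kB list alone, neither over all genes (edgeR adjusted p = 0.143 for IL1B and 0.998 for CD83). IL1B in dendritic cells did pass over all genes with no filter on low counts (adjusted p = 9.02e-04) and without habitual-sleep participant 2 (adjusted p = 0.00753), and CD83 in no alternative. Both were chosen after their values were seen, and so was their list, which was lower in 13 of 19 members and did not pass (camera adjusted p = 0.193). Counted per list, 7 members passed adjusted over their list alone in dendritic cells. The sums rested on 181, 23, 30 and 102 dendritic cells of habitual-sleep participants 1 to 4 and 27, 75, 37 and 79 of sleep-restriction participants 5 to 8.

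The B cell genes were followed into other classes by their CPM over the summed UMIs of each group. CLECL1 was at 31.5 in habitual sleep and 74.0 in sleep restriction in B cells, 16.6 and 30.3 in dendritic cells, 7.32 and 16.5 in nonclassical monocytes, 6.06 and 9.25 in classical monocytes and 1.54 and 6.96 in CD4 T cells. In NK cells it was at 0 and 4.04, so it was higher in sleep restriction in each class counted. DSP was at 28.9 and 4.49 in B cells and at 0.691 or less in the other 5 classes counted, 0 of 1991 and 0 of 2297 cells having a UMI in CD4 T cells. These sums were not tested.

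Whether chance could give as many calls was asked by counting the 35 splits of the 8 participants into 2 groups of 4, the real one included. In B cells 3 of 35 splits gave at least the 2 genes of the real split, with 6 as the highest of the others, so chance cannot be excluded. In classes with a real count of 0, all 35 splits gave as many by definition; the highest other split gave 1 gene in monocytes, 7 in classical monocytes, 6 in nonclassical monocytes, 58 in CD4 T cells, 315 in CD8 T cells, 25 in NK cells and 6 in dendritic cells. For the monocyte-lymphocyte difference (real count 0, 35 of 35 splits) it was 3. Splits that call 315 and 58 genes point to a possible structure among the participants other than their groups, which was not tested. For lists, chance cannot be excluded in the 7 classes with a call. At least as many passed in 31 of 35 splits in monocytes (real 7, median of the other splits 11, highest other 17). It was 30 in classical monocytes (6, 9 and 15), 28 in nonclassical monocytes (5, 6.5 and 13) and 25 in CD4 T cells (3, 4 and 15). For CD8 T cells it was 21 (5, 5 and 17), for NK cells 26 (3, 4 and 11) and for B cells 11 (5, 3 and 9). The real split gave fewer lists than the median of the others in monocytes, both monocyte subsets, CD4 T cells and NK cells. It gave as many in CD8 T cells and more in B cells. In dendritic cells the real count was 0, so all 35 splits gave as many by definition, and the highest other split gave 11.

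In monocytes, the ribosomal protein list was called higher and the immediate-early list lower under sleep restriction with the preset correlation, but neither with an estimated one (adjusted p = 0.788 and 0.809), and 0 members passed. For both lists, cells of 2 habitual-sleep preparations (participants 1 and 4, each with most of a monocyte cluster) are a candidate explanation. Without both, which leaves 2 habitual-sleep participants, the immediate-early median went from -0.45 to -0.14, below the bound set for it. It was already -0.13 without participant 4 alone, and the call held without participant 1 alone. The value with both left out therefore does not tell 2 preparations apart from participant 4 alone. The ribosomal median stayed at 0.193 without both but was 0.104 without participant 1 alone and 0.302 without participant 4 alone, so for it the explanation cannot be told apart from others. The tests of the 2 lists were first stated as 1 joint test, neither of whose bounds was met, and were restated per list after that result was seen. Depth of the kept cells is argued against for the ribosomal list by the ratio of median UMIs per kept monocyte, 1.08, within the 1.2 times set for it. Over every deposited barcode, the median monocyte held 4004 UMIs in habitual sleep and 6796 in sleep restriction, outside that bound. Ribosomal protein UMIs there were at 9.07% in habitual sleep and 17.5% in sleep restriction and mitochondrial UMIs at 24.4% and 8.73%, so the state of the cells stays open. A response to sleep stays open and untested, since other differences between the 8 people follow the groups too.

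For DSP and CLECL1 in B cells, another mix of naive and memory B cells is a possible explanation. The level of 8 memory markers minus that of 8 naive markers was higher in sleep restriction by log2 0.509, above the 0.5 set beforehand, but its exact permutation p was 0.257, so this stays open. A mix of B cells would not give the higher CLECL1 sums seen in the other classes counted, though those sums were not tested. Genotype of single participants was not examined and stays open, as does sleep.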
